A study of Mus musculus with 8 samples.

How the data were processed

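Bone marrow B cells of 4 control and 4 miR-15 dKO mice were profiled by RNA sequencing, and samples were grouped by the genotype in their titles. Per the labels' protocols, RNA was isolated with a column kit, amplified and reverse transcribed by SMART-seq, and made into libraries with a SMARTER kit. Per the submitters' processing notes, reads were handled with Trimmomatic, STAR and featureCounts on the GRCm39 build. Their versions, the annotation and the strand setting are not given in the sources used here. The authors deposited raw read counts per gene, not scaled, in 1 table for all libraries. Its columns were assigned through the column codes in the sample descriptions, and 3 unnamed summary columns were not used. The table holds 24746 genes, of which 9295 have no count in any library, 840 have no Ensembl identifier and 13 have symbols turned into calendar dates by a spreadsheet. No rows of immunoglobulin segments, T cell receptor segments or mitochondrial genes were analysed here. Among counts below 20, 72.7% to 77.3% of the values per library are even, as when both mates of a read pair are counted. If so, the number of fragments is lower than the count, and the fits were repeated on halved counts. Genes with near-identical copies may have lost or shared reads in counting.

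Depth was 25565090 to 34954230 counts per library. The 10 most abundant genes took 16.7% to 19.9% of the counts and Rn45s, a ribosomal RNA gene, 0.36% to 1.83%. A level of 3 counts corresponds to 0.0854 to 0.111 CPM, which covers counting error only, since reads were not tied to single molecules. The series text gives 4 mice per group. Within groups, chi-square per degree of freedom over genes with at least 20 counts was 31.3 to 321.3, so no pair of libraries was a duplicate within sampling noise.

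Genes were filtered with filterByExpr, which left 11363, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment. CPM values are relative to TMM-scaled totals and log2 CPM values use a prior count of 2. The standard error of a log2 fold change was taken from the fold change and the F statistic. Fold changes are dKO over control. On simulated counts with the means and dispersions of these libraries (11363 genes, 5 simulations), 6.5% of genes changed 1.5-fold, 37.5% of those changed 2-fold and 80.0% of those changed 4-fold were recovered, and 4.7% of the calls were false. Lists of at least 3 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01, adjusted over 19 lists), and again with an estimated correlation and with fry. In the simulations a list raised 1.5-fold was called in 5 of 5, and of 89 tests of other lists 1 passed. Genes were drawn independently there, while list members vary together in the libraries (estimated correlation 0.74 for T cell markers and 0.50 for follicular B-2 markers). The simulations therefore do not show how often camera with the preset correlation calls such lists falsely.

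The 20 lists, fixed before the data were examined, were the miR-15/16 loci and host genes (2 tested members, not tested as a list), literature miR-15/16 targets, IL-7 receptor and STAT5 signalling, G1/S entry, proliferation, BCL2 family, B-cell receptor signalling, MHC class II presentation, type I interferon response, immediate early and heat shock genes and glycolysis, together with markers of B-1a, pro-B, follicular B-2, marginal zone B, plasma, T, myeloid, erythroid and NK cells. The lists overlap. Tnfrsf13b is both a B-1a and a plasma cell marker, Bcl2 is in the literature target, signalling and BCL2 family lists, and T cells express Cd5 and Ctla4.

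Seed matches were searched in 3′ UTRs of GENCODE M21 protein-coding transcripts (GRCm38), at least 7 bases long, matched by Ensembl identifier and otherwise by symbol. Since this is another build than the authors', no coordinates are given. Of the genes tested, 10668 (93.9%) had an annotated 3′ UTR, and genes without one were left out. The search took the longest 3′ UTR, and the permutation ran over all 35 splits of the 8 libraries into 4 and 4. All 210 heptamers with the bases of the seed match, itself included, served as a background.

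Named genes followed a rule set before the data were examined. It takes Il7r and the measured genes of the targeted loci, then up to 12 genes per direction with the largest fold change among those with adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups (immunoglobulin segments, Xist, Y-linked genes and unnamed gene models left out), then up to 4 members with the smallest p in each list. Other genes are said to be chosen after their values were seen. Alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma voom with quality weights, no filter, CPM above 5 in at least 4 libraries, an adjusted p under 0.1, a sex term, a replicate block and leaving out each library. Halved counts, leaving out control 2 and control 4, and the follicular B-2 score as a covariate were added after seeing the data. Python 3.11.15 with pandas 2.3.3 was used for reading and matplotlib 3.10.9 for plots.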

Results

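RNA sequencing was carried out on B cells sorted from the bone marrow of 8 mice aged 10 to 12 weeks. In 4 of the mice both miR-15/16 clusters, miR-15a/16-1 on 1 chromosome and miR-15b/16-2 on another, carried loxP sites on both alleles (miR-15 dKO, below dKO), and 4 mice with wild-type clusters served as controls. Both genotypes carried Vav-Cre, a transgene that expresses Cre recombinase in blood-forming cells and their descendants. The miR-15/16 microRNAs share 1 seed sequence and repress transcripts that match it in the 3′ UTR, cell cycle and survival genes among the known ones. By its title, the series concerns IL-7 receptor expression and early B cell development. RNA was amplified with the SMART-seq protocol, which copies full-length cDNA from small amounts of RNA, and the deposited values were read counts per gene. Each library had a total of 25565090 to 34954230 counts, and 12489 to 13430 genes had at least 1 count.

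The libraries carried a mature B cell profile that included the markers of B-1a cells, an innate-like, long-lived B cell type. Cd79a, a subunit of the B cell receptor, stood at 13775 ± 1699 CPM (counts relative to the scaled library total, SD, n = 4) in the controls and at 13137 ± 753 (SD, n = 4) in the dKO libraries. All 16 B-1a markers had a mean of at least 1 CPM, and 12 of them were above 10 CPM. So were 12 of 13 follicular B-2 markers, none of them under 1 CPM, so these counts do not tell B-1a cells from conventional B cells. Of 19 pro-B markers, 10 were under 1 CPM. Rag1, which starts antigen receptor recombination in pro-B cells, had a mean of 0.034 CPM in the controls and no count in the dKO libraries, and Igll1, a surrogate light chain gene, stood at 0.38 and 0.23 CPM. The sample labels call the cells B1a B cells while the series text calls them pro-B cells, and these levels are those of the libraries under the B1a label. Cd79a, Rag1 and Igll1 were chosen after their values were seen.

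Transcripts of other cells were present and varied among the libraries of 1 genotype. Lyz2, a lysozyme gene of macrophages and neutrophils, was at 2498 ± 1953 CPM in the controls and 1121 ± 715 CPM in the dKO libraries (SD, n = 4 each, edgeR adjusted p = 0.63). Follicular B-2 markers, the genes of conventional recirculating B cells, had a mean log2 CPM of 7.34 in control 2 and 7.42 in control 4. The other 6 libraries, control 1 and control 3 among them, lay between 5.76 and 6.28. NK cell markers had their lowest means in control 1 (0.19) and control 3 (−0.66), against 1.62 to 2.81 in the other 6 libraries, and T cell markers were likewise lowest in control 1 (2.46) and control 3 (1.41), against 2.71 to 3.62. The Y-linked gene Ddx3y was expressed in control 1, dKO 3 and dKO 4, and the other 5 libraries carried Xist, the transcript of the inactive X chromosome.

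Dleu2, the long non-coding host transcript of miR-15a and miR-16-1, was 5.02-fold higher in the dKO libraries than in the controls. It stood at 90.3 ± 16.3 CPM against 17.96 ± 5.95 CPM (SD, n = 4 each), with a log2 fold change of 2.33 ± 0.24 (SE, edgeR adjusted p = 0.0065), and the dKO libraries all lay above the controls. Smc4, the condensin gene that hosts miR-15b and miR-16-2, was at 134.2 ± 24.2 CPM in the dKO libraries and 126.6 ± 39.2 CPM in the controls (SD, n = 4 each), a log2 fold change of 0.08 ± 0.23 (SE, adjusted p = 0.94). The 4 precursor genes Mir15a, Mir16-1, Mir15b and Mir16-2 had 0 counts in all 8 libraries, where 3 counts correspond to 0.0854 to 0.111 CPM. Host transcripts outside the deleted parts do not show whether a microRNA was removed, so the genotype labels were not checked by these genes. Trim13 and Kcnrg overlap Dleu2 on the opposite strand in the GRCm38 annotation, and the strand setting of the counting is not given in the sources used here. Trim13 was at 5.0 ± 1.9 against 4.0 ± 1.9 CPM and Kcnrg at 0.80 ± 0.24 against 0.22 ± 0.16 CPM (SD, n = 4 each, adjusted p = 0.83 and 0.43), both chosen after their values were seen.

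Beside Dleu2, the named genes that rose in the dKO libraries were the kinase gene Pim1, the inhibitory receptor gene Ctla4 and Platr17, a gene annotated as protein-coding in the reference used here, and Fam212a, Rhobtb1 and Mgme1 fell. Pim1, a target of cytokine signalling through STAT5, was at 64.7 ± 7.35 CPM in the dKO libraries and 20.2 ± 6.66 CPM in the controls (log2 fold change 1.68 ± 0.21, SE, adjusted p = 0.011). Ctla4, expressed by T cells and by B-1a cells, was at 34.0 ± 6.33 against 10.6 ± 4.19 CPM (1.68 ± 0.26, adjusted p = 0.045), and Platr17 at 36.1 ± 4.74 against 14.5 ± 1.65 CPM (1.32 ± 0.16, adjusted p = 0.0080). Rhobtb1, which encodes a protein with BTB domains, was at 3.27 ± 0.72 CPM in the dKO libraries and 14.3 ± 3.30 CPM in the controls (−2.13 ± 0.25, adjusted p = 0.0080). Fam212a was at 22.2 ± 2.42 against 52.1 ± 4.11 CPM (−1.23 ± 0.14, adjusted p = 0.0080), and Mgme1, a nuclease of mitochondrial DNA maintenance, at 8.37 ± 1.69 against 20.8 ± 1.97 CPM (−1.32 ± 0.19, adjusted p = 0.034). Of 11363 genes tested, 7 rose and 3 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test), and 1229 had an unadjusted p under 0.05. In 791 of the genes tested (7%) the 2 groups did not overlap, where chance gives 2.9%, and all 10 called genes were among them. The other 3 genes that rose lie outside the rule for named genes and were named after their values were seen. Ackr2, an atypical chemokine receptor gene, had a log2 fold change of 2.11 ± 0.31 (SE), and the gene model Gm2447 one of 1.92 ± 0.29. Acoxl, an acyl-CoA oxidase-like gene, had no count in any control and 1.51 ± 0.74 CPM (SD, n = 4) in the dKO libraries. That is at least 13.8-fold above the level of 3 counts in a control library, if each count is 1 fragment. The bound is lower if both mates of a read pair were counted.

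**Figure D1:**
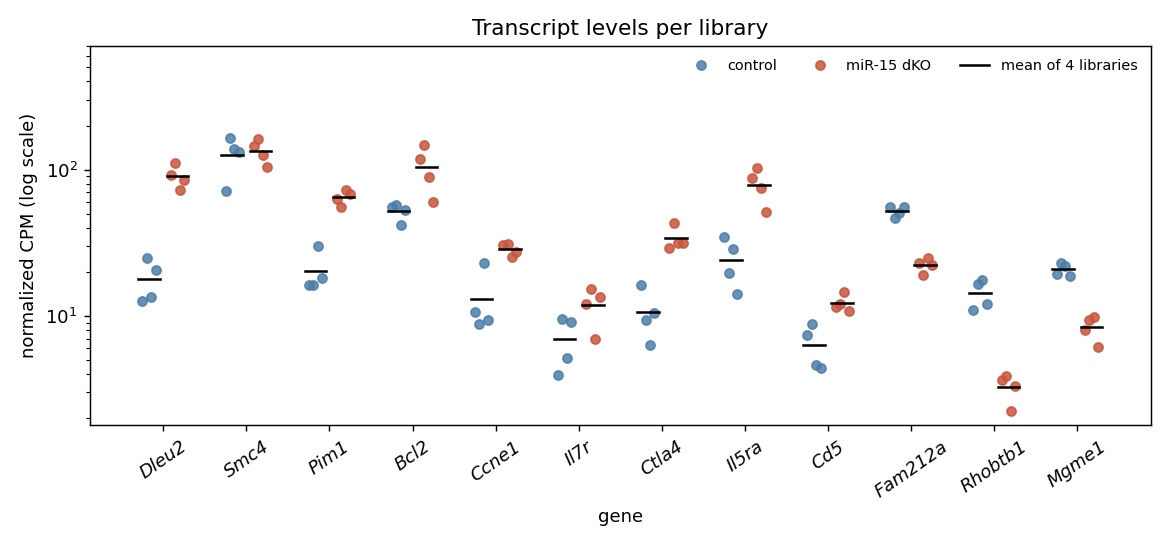
Normalized CPM (log scale) of 12 genes in each of the 4 control (blue) and 4 miR-15 dKO (red) libraries, with black bars for group means. Dleu2, Pim1 and Ctla4 lie higher and Fam212a, Rhobtb1 and Mgme1 lower in the dKO libraries without overlap, while Smc4 and Il7r overlap between the groups.

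The number of genes past the threshold depended on the libraries and on the tool. It was 98 without control 1, 18 without control 2, 30 without control 3 and 4 without dKO 2, dKO 3 or dKO 4, while DESeq2 called 324 genes and limma voom with quality weights 257. Without control 2 and control 4, the libraries with high follicular B-2 markers, edgeR called 59 genes, 22 higher and 37 lower. Dleu2 and Fam212a were called in each of the 19 alternative fits. Rhobtb1 lost its call without dKO 4 (adjusted p = 0.052), Platr17 without dKO 2 (0.051), and Pim1 without control 4 (0.059), dKO 3 (0.065) or dKO 4 (0.052). Mgme1 and Acoxl lost theirs without control 4 or any 1 dKO library. Ackr2 did so without control 4, dKO 1, dKO 2 or dKO 3, and Gm2447 without control 3 or any 1 dKO library. Ctla4 kept its call in only 7 of the 19 fits. It lost it without control 2, control 4 or any 1 dKO library and with RLE or upper quartile scaling (adjusted p = 0.051 each). CPM above 5 in at least 4 libraries (0.067) and a replicate block (0.06) also removed it. So did leaving out both control 2 and control 4 (0.086) and the follicular B-2 score as a covariate (0.051). Ackr2 lost its call in both of these last fits (0.055 and 0.051), and Acoxl and Gm2447 with the covariate (0.051 each). Acoxl also lost its call with halved counts (0.051). The replicate block also removed the calls of Platr17 and Mgme1 (0.05 each, not under the threshold), Ackr2 (0.06), Gm2447 (0.071) and Acoxl (0.11). With a library left out, the adjusted p of Ctla4, Ackr2, Acoxl, Gm2447 and Mgme1 was at most 0.18.

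Genes known as targets of miR-15/16 lay higher as a group in the dKO libraries. The list was taken from the literature before the data were examined. Of its 22 tested members 15 had a positive and 7 a negative log2 fold change, with a median of 0.37 (camera with a preset correlation, adjusted p = 0.0036 over 19 lists). The adjusted p was 0.24 with an estimated correlation, 0.071 in fry and 0.18 without control 2 and control 4, where the median was 0.29. As small a list p (camera, 3.8e-04 unadjusted) came from 4 of 35 splits of the libraries, so chance is not excluded. Leaving out 1 library kept the call but moved the median between 0.18 (without dKO 3) and 0.46 (without control 3), with 0.19 without control 4 and 0.22 without control 2 or dKO 2, and it was 0.14 without a filter. No member passed over all genes tested, and 3 rose when adjusted over the list alone. Arl2, a small GTPase of tubulin folding, was at 213.7 ± 16.6 against 116.1 ± 21.3 CPM (SD, n = 4 each), a log2 fold change of 0.88 ± 0.16 (SE, adjusted p = 0.069). Bcl2, which blocks apoptosis, was at 104.1 ± 37.9 against 51.9 ± 6.83 CPM (1.00 ± 0.24, adjusted p = 0.13), and Ccne1, the cyclin E1 gene of S phase entry, at 28.5 ± 2.61 against 12.96 ± 6.70 CPM (1.14 ± 0.28, adjusted p = 0.14). Arl2 passed over all genes without control 1 (adjusted p = 0.034) and Ccne1 without control 3 (0.014), and DESeq2 and limma voom called all 3. These calls are not particular to the targets, since DESeq2 called 324 genes. The follicular B-2 marker Icosl was among them (DESeq2 adjusted p = 0.012). Its edgeR log2 fold change was −0.28 (adjusted p = 0.88) without control 2 and control 4. In the list score, the mean log2 CPM of its members, control 3 (3.37) lay above dKO 4 (3.28) and level with dKO 3 (3.37), and the other controls lay between 2.84 and 3.01.

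Il7r, the gene named by the study's question, was at 12.0 ± 3.61 CPM in the dKO libraries and 6.93 ± 2.80 CPM in the controls (SD, n = 4 each). Its log2 fold change of 0.79 ± 0.32 (SE) did not pass over all genes (adjusted p = 0.40) and the groups overlapped. The log2 fold change was 1.39 (adjusted p = 0.10) without control 2 and control 4 and 1.23 (0.10) with the follicular B-2 score as a covariate, and 0.61 to 0.98 (adjusted p = 0.25 to 0.73) with 1 library left out. Without control 2 and control 4 the T cell and NK cell lists had medians of 1.25 and 1.73. Il7r counts were lowest in control 1 (109) and control 3 (146) among the controls and in dKO 3 (203) among the dKO libraries. These libraries also had the lowest T cell scores of their groups (2.46, 1.41 and 2.71). Whether T cells carry part of the Il7r difference was not tested. IL-7 receptor and STAT5 signalling had 12 of 17 members with a positive log2 fold change and a median of 0.16 (camera adjusted p = 0.056, and 0.24 with an estimated correlation). Pim1 rose over all genes tested, and Pim1 and Bcl2 rose when adjusted over the list alone. Socs2, a feedback inhibitor of this pathway, went the other way at 2.83 ± 0.36 against 6.95 ± 5.43 CPM (SD, n = 4 each, log2 fold change −1.29 ± 0.47, SE, adjusted p = 0.33). Socs2 was called lower without control 2 and control 4 (−1.94, adjusted p = 0.023) and with the follicular B-2 score as a covariate (−1.68, 0.028). Leaving out 1 library moved the median between 0.09 (without control 4) and 0.29 (without control 3), with 0.10 without dKO 3, 0.24 without dKO 2 and 0.25 without dKO 4. The list passed without control 3 (adjusted p = 0.016), dKO 2 (0.032) or dKO 3 (0.040), without a filter (0.048), with CPM above 5 in at least 4 libraries (2.2e-04), with a sex term (0.042), with halved counts (0.039) and in fry (0.041). It did not pass without control 1 (adjusted p = 0.23) or without control 2 and control 4 (0.18).

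Among cell cycle genes the members of the G1/S list did not pass as a group. Of its 18 tested members 11 had a positive log2 fold change, with a median of 0.17 (camera adjusted p = 0.061, and 0.35 with an estimated correlation). None passed over all genes, and 2 rose when adjusted over the list alone, Ccne1 and Cdkn2c. Cdkn2c, which inhibits CDK4 and CDK6 and thus acts against S phase entry, was at 90.5 ± 23.3 against 41.3 ± 11.1 CPM (SD, n = 4 each, log2 fold change 1.13 ± 0.22, SE, adjusted p = 0.084), and at 0.017 without control 1. The list passed without control 3 (adjusted p = 0.0045) or dKO 3 (0.017), without a filter (0.048), with CPM above 5 in at least 4 libraries (0.0093) and with halved counts (0.020). Proliferation genes of S, G2 and M phase showed no joint shift, with 14 of 30 members positive, a median of −0.08, a mean of 0.09 and a test in the upward direction (adjusted p = 0.72). Leaving out 1 library moved that median between −0.21 (without control 4) and 0.26 (without control 1), without a call (camera adjusted p of at least 0.15). Mki67 had low levels in both groups and lay higher in the dKO libraries, at 4.70 ± 2.59 against 1.24 ± 0.80 CPM (SD, n = 4 each, log2 fold change 1.92 ± 0.54, SE, adjusted p = 0.19). Tpx2, the member with the smallest p, also lay higher (1.165 ± 0.32, adjusted p = 0.18). Mcm5, of the replicative helicase, lay lower, at 5.97 ± 0.80 against 9.27 ± 1.19 CPM (−0.64 ± 0.20, adjusted p = 0.24). Without control 2 and control 4 the proliferation list was called lower, with a median of −0.26 (adjusted p = 0.029, and 0.54 with an estimated correlation). The BCL2 family had 9 of 16 members positive, with a median of 0.04, a mean of −0.08 and an upward test (adjusted p = 0.83), and only Bcl2 rose when adjusted over the list alone. Bcl2a1a, at 1.63 ± 0.65 against 3.64 ± 1.56 CPM (SD, n = 4 each, adjusted p = 0.37), has near-identical copies, so its counts are uncertain.

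B-1a markers were the gene group with the clearest rise in the dKO libraries. Of 16 members 13 had a positive log2 fold change, with a median of 0.65 (camera adjusted p = 5.5e-10, and 0.13 with an estimated correlation). Ctla4 rose over all genes tested, and 7 members rose when adjusted over the list alone. Il5ra, the IL-5 receptor chain through which B-1 cells are maintained, was at 79.0 ± 21.6 against 24.2 ± 9.01 CPM (SD, n = 4 each, log2 fold change 1.71 ± 0.29, SE, adjusted p = 0.069). Tnfrsf13b, which encodes the BAFF and APRIL receptor TACI, was at 237.3 ± 58.2 against 116.8 ± 20.3 CPM (1.02 ± 0.20, adjusted p = 0.085), and Cd5, the surface marker that defines B-1a cells, at 12.2 ± 1.66 against 6.29 ± 2.12 CPM (0.96 ± 0.25, adjusted p = 0.15). Without control 1, Il5ra and Tnfrsf13b passed over all genes (adjusted p = 0.021 and 0.049). The list score lay between 5.79 and 5.90 in the dKO libraries, above all 4 controls. Control 2 (4.90) and control 4 (4.82), with the high follicular B-2 markers, had the lowest scores, and control 1 (5.52) and control 3 (5.35) lay between. Without control 2 and control 4 the median was 0.39 and the list still passed (adjusted p = 0.0087), though not with an estimated correlation (0.25). In that fit the T cell and NK cell lists had higher medians, 1.25 and 1.73. Without 6 B-1a members that T cells also express, the median of the 10 left was 0.275 ± 0.174 (SE over members). Whether T cells express some of these 10 was not tested.

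Follicular B-2 markers were lower in the dKO libraries than in the mean of the controls, through 2 control libraries. Of 13 tested members 11 had a negative log2 fold change, with a median of −0.40 (camera adjusted p = 0.025, and 0.93 with an estimated correlation), and none passed over all genes or when adjusted over the list alone. The chemokine receptor gene Ccr7, which guides cells into lymph nodes, was at 840.9 CPM in control 2 and 370.1 CPM in control 4, at 144.8 and 78.7 CPM in control 1 and control 3, and between 68.7 and 147.8 CPM in the dKO libraries (adjusted p = 0.38). Icosl, the ICOS ligand gene, followed the same split, with 9.26 and 9.68 CPM in control 2 and control 4 and 0.65 to 1.55 CPM in the other 6 libraries (adjusted p = 0.23). The list lost its call without control 2 (median −0.24, adjusted p = 0.24), control 4 (−0.23, 0.24) or dKO 1 (−0.35, 0.060), and also with CPM above 5 in at least 4 libraries (−0.14, 0.17), with a sex term (−0.31, 0.16) and in fry (0.84). Without both control 2 and control 4 its median was 0.05 (adjusted p = 0.24).

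**Figure D2:**
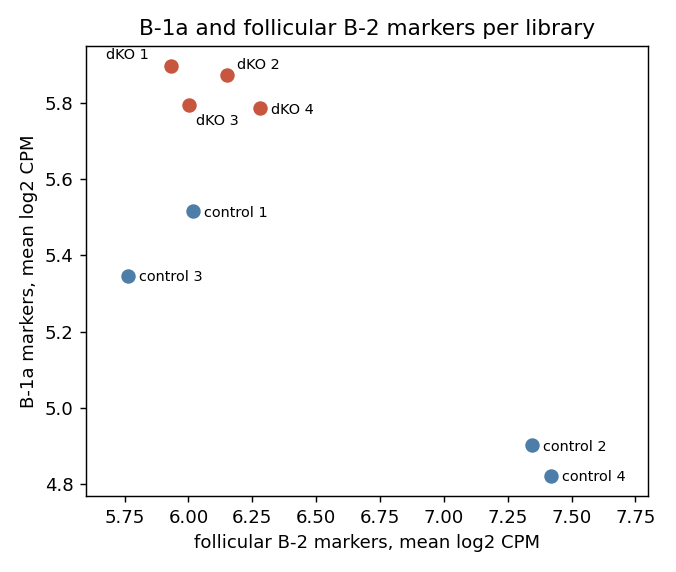
Mean log2 CPM of the B-1a markers (vertical axis) against that of the follicular B-2 markers (horizontal axis) in each library, controls in blue and miR-15 dKO in red. Control 2 and control 4 lie apart at 7.34 and 7.42 on the horizontal axis, and the 4 dKO libraries lie at 5.79 to 5.90 on the vertical axis, above all controls.

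Other cell type lists did not pass. Pro-B markers had 7 of 10 tested members positive, with a median of 0.09, a mean of −0.17 and an upward test (adjusted p = 0.72), and Vpreb3, at 14.4 ± 13.1 against 101.3 ± 87.2 CPM (SD, n = 4 each, log2 fold change −2.81 ± 0.80, SE, adjusted p = 0.23), was highest in control 4 at 227.7 CPM. Marginal zone markers had a median of −0.12 (adjusted p = 0.65). Plasma cell markers had a median of 0.15 (adjusted p = 0.13), and 3 of 16 members rose when adjusted over the list alone, Tnfrsf13b, Prdm1 and Mzb1. Prdm1, the regulator of plasma cell differentiation, was at 4.42 ± 0.60 against 1.76 ± 0.90 CPM (SD, n = 4 each, adjusted p = 0.20). T cell markers had a median of 0.25 (adjusted p = 0.12) and passed upward without control 2 (median 0.58, adjusted p = 0.0073), control 4 (0.34, 0.034) or dKO 3 (0.36, 0.0086). The T cell median was near 0 without control 3 and 0.04 without dKO 4 (adjusted p = 0.91 and 0.39). NK cell markers had a median of 0.23 (adjusted p = 0.21) and passed without control 2 (median 0.92, adjusted p = 0.014), while the median was −0.17 without control 1, −0.13 without control 3 and near 0 without dKO 4 (adjusted p = 0.63, 0.86 and 0.39). Without both control 2 and control 4 the T cell and NK cell lists had medians of 1.25 and 1.73 (adjusted p = 5.9e-06 and 1.2e-06, and 0.54 and 0.25 with an estimated correlation). Myeloid and erythroid markers had medians of −0.23 (adjusted p = 0.96) and −0.18 (0.65), the second over 3 tested members. Of these, Car2 (carbonic anhydrase 2) fell when adjusted over the list alone. Its counts were highest in control 2 (459) and control 4 (302). Without both, its log2 fold change went from −1.475 to −0.456 (edgeR adjusted p = 0.64).

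The lists of B cell function and stress also did not pass. B-cell receptor signalling had 9 of 23 members positive, with a median of −0.05, a mean of −0.02 and an upward test (adjusted p = 0.84). Nfatc1, a transcription factor downstream of that receptor, was at 66.5 ± 5.47 against 44.6 ± 7.52 CPM (SD, n = 4 each, log2 fold change 0.58 ± 0.15, SE, adjusted p = 0.15). MHC class II presentation had a median of −0.18 (adjusted p = 0.39) and passed downward without control 3 (0.024). Its median was 0.26 and the test upward without control 2 and control 4 (adjusted p = 0.13). Type I interferon response genes had a median of −0.17 (adjusted p = 0.72) and glycolysis genes one of −0.01 (0.72). Immediate early and heat shock genes had a median of −0.20 (adjusted p = 0.17) and passed downward without control 1 (0.019) or control 3 (0.0045). Without control 2 and control 4, which had the highest scores of that list (4.27 and 4.11, against 2.93 to 3.63 in the other 6 libraries), its median was 0.34 and the test was upward (adjusted p = 0.18). The 2 members that fell when adjusted over the list alone were the chaperone genes Hsph1, at 10.1 ± 1.04 against 23.7 ± 9.40 CPM (log2 fold change −1.24 ± 0.29, SE, adjusted p = 0.12), and Dnajb1, at 36.1 ± 6.04 against 58.9 ± 14.8 CPM (−0.70 ± 0.20, adjusted p = 0.20, SD, n = 4 each). Hsph1 was called over all genes without control 1 (adjusted p = 0.0047).

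**Figure D3:**
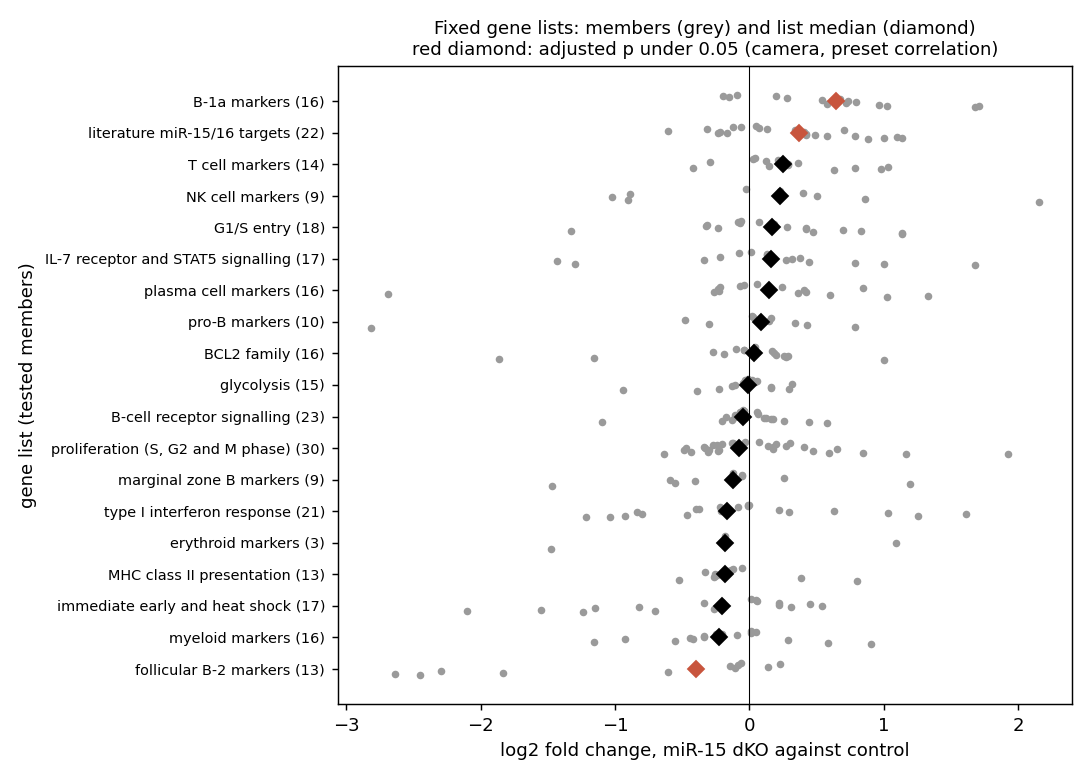
Log2 fold changes (miR-15 dKO against control) of the tested members of 19 fixed gene lists (grey points) and list medians (diamonds), red where the adjusted p was under 0.05 in camera with a preset correlation. B-1a markers (median 0.65) and literature targets (0.37) lie to the right and follicular B-2 markers (−0.40) to the left.

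Transcripts with a match to the miR-15/16 seed in the 3′ UTR lay slightly above those without one. The median log2 fold change was 0.02 over 2622 genes with a 7mer-m8 (TGCTGCT) or 8mer match (TGCTGCTA) in the longest annotated 3′ UTR and −0.05 over 5901 genes without a 6mer match (GCTGCT), a difference of 0.07. It was 0.035 without control 1, 0.117 without control 2, 0.108 without dKO 4 and 0.111 without control 2 and control 4. In an exact two-sided permutation over the 35 splits of the libraries into 4 and 4, p was 0.31, where the smallest p the design allows is 0.029, and camera gave p = 0.25 (0.51 with an estimated correlation). The difference was 0.11 over the 476 genes with an 8mer match. Of the 22 tested literature targets 21 carry a 7mer-m8 or 8mer match. Of the 10 genes past the threshold 7 have an annotated 3′ UTR, and 2 of these carry a match. That is near the share of all tested genes with an annotated 3′ UTR, 2622 of 10668. Pim1 has 2 7mer-m8 matches in 1365 bases and Ackr2 has 1 in 1377 bases. Ctla4, Mgme1 and Acoxl carry none, Platr17 and Rhobtb1 carry a 6mer match only, and Il7r carries 1 8mer match in 2569 bases.

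**Figure D4:**
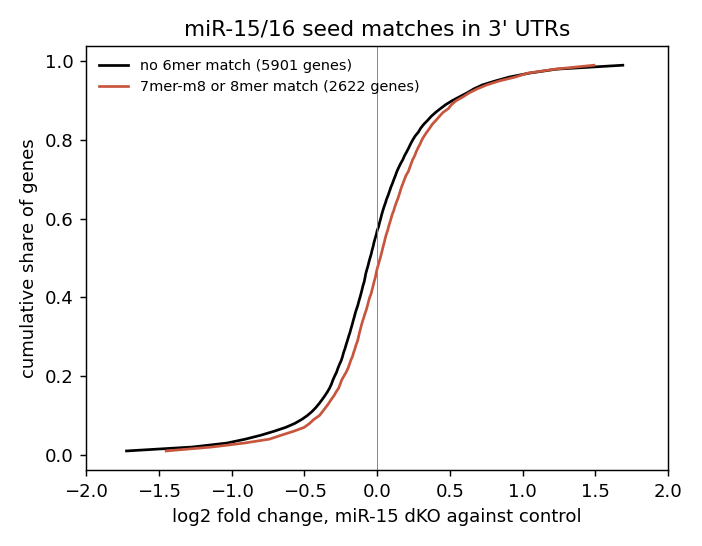
Cumulative share of genes by log2 fold change (miR-15 dKO against control) for 2622 genes with a 7mer-m8 or 8mer seed match (red) and 5901 genes without a 6mer match (black). The red curve lies to the right by 0.07 at the median.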

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

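The tests on sex, on T cells and on follicular B cells in control 2 and control 4, and the counts of splits except those of the follicular list, DESeq2 and limma voom, were chosen after the result was seen; the tests on 3′ UTR length and base composition came before.

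In 12 of 196 groups of 4 libraries, 1 library stood far from the other 3 in the level of a named gene or a list, where chance gives about 9.8 (1 in 20). The gap divided by the range is given for each. Control 3 was high for Pim1 (0.83, log2 CPM 4.92 against 4.03 to 4.18) and low for Bcl2a1a (0.98, 0.45 against 2.15 to 2.18) and Klrk1, an NK cell receptor gene (0.833, −1.26 against 1.45 to 1.99). The G1/S list score was high in control 3 (0.915, 4.01 against 3.73 to 3.75), and control 1 was low for the chaperone gene Hsph1 (0.834, 3.35 against 4.71 to 4.99). Among the dKO libraries, dKO 3 was low for Mcl1, a survival gene (0.864), Usp18, an interferon response gene (0.85), and the chaperone gene Dnajb1 (0.854). The glycolysis genes Pgk1 (0.931, 6.47 against 5.87 to 5.91) and Ldha (0.907, 9.39 against 8.61 to 8.68) were high in dKO 4, the T cell factor gene Tcf7 (0.876) in dKO 2 and Fosb (0.846) in dKO 1.

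The list p of the rise of the B-1a markers (2.9e-11) was reached by 1 of 35 splits of the libraries, the real one. The smallest of the others was 8.8e-07. Chance is unlikely for this rise but not excluded, since 35 splits allow no p below 0.029. The follicular B-2 list reached 6.9e-10 in another split. The B-1a list was tested here after it was seen to have the smallest p. That p was not compared with the smallest p of any list in each split. T cells also express 6 of the 16 B-1a members. These 6 are argued against as the whole source, since the median of the 10 members left was 0.647 ± 0.16 (SE over members). That is above 0.324, 0.5 times the value of the full list. Whether T cells express some of the 10 was not tested. Sex is argued against by a median of 0.608 with a sex term. Against control 1 and control 3 alone, which had the lowest T cell scores, T cells cannot be told apart from a genotype effect, since the median of these 10 members was 0.275 ± 0.174 (SE), within its error of 0.193, 0.5 times the value of the full list in that fit. Follicular B cells in control 2 and control 4 cannot be told apart from a genotype effect for part of the rise, since the median without these libraries, 0.385 ± 0.20 (SE), lies within its error of 0.324. Each SE here is over list members and does not cover the spread between mice. A genotype effect stays open.

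The lower follicular B-2 markers rest on those control libraries. Without control 2 and control 4 the median went from −0.40 to 0.05. These libraries were left out for their high scores of this same list, so the rise of the median was built in and does not test a cause. Follicular B cells in the sorted cells of these 2 mice stay a candidate. Ccr7, an abundant member, and Icosl show the same split of the controls. As small a list p (0.0039) came from 15 of 35 splits, with 6.9e-10 the smallest of the others, so chance is not excluded. A change in the controls' B cells of another kind was not tested.

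The shift of seed-match genes was as large in 11 of 35 splits (real difference 0.070, highest other 0.161), so chance is not excluded. Against genes matched on 3′ UTR length and expression the difference was 0.053 ± 0.010 (bootstrap SE). That is above 0.0352, 0.5 times the unmatched one, which argues against those properties as the whole cause in these libraries. Differences of up to 0.161 in other splits lie beyond this SE, which does not cover the spread between mice. The match ranked 7 among 210 heptamers of the same bases, with a 95% bootstrap range of 5 to 36, so base composition cannot be told apart from the seed: the range reaches past the 10 highest. Loss of miR-15/16 repression predicts the direction seen and may add to it, but these splits do not separate it from differences between mice.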

How the results depend on the processing

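Halved counts, the follicular B-2 covariate, leaving out control 2 and control 4 (with either correlation), and the sex term and upper quartile scaling for lists were chosen after the result was seen. Removing immunoglobulin genes was not run, since no such rows were analysed here. The cause was not tested except where it is stated. The 10 genes called (7 higher, 3 lower) became 40 (30 and 10) without a filter, 7 (4 and 3) with CPM above 5 in at least 4 libraries, where Ackr2 and Acoxl were not tested, 59 (22 and 37) without control 2 and control 4, 23 (14 and 9) with the covariate, 324 (199 and 125) in DESeq2, 257 (158 and 99) in limma voom and 75 (51 and 24) at an adjusted p under 0.1. Leaving out 1 library gave 4 to 98 genes, 2 to 74 higher and 1 to 24 lower. DESeq2 and limma voom also called genes in other splits, up to 209 and 102. RLE and upper quartile scaling, halved counts (9 each) and the sex term (13) left the count near 10.

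The replicate numbers did not pair the libraries (correlations of same-numbered deviations −0.009, −0.071, 0.061 and 0.149, and not every library correlated best with its own number). With the replicate block, 9 genes were called, 4 of them among the 10, and 7 lists. The 3 lists called became 0 with an estimated correlation (with all libraries or without control 2 and control 4), 5 without a filter or with halved counts, and 2 to 7 with 1 library left out. The literature targets no longer passed with an estimated correlation or fry (median 0.37) or without control 2 and control 4 (0.29), and leaving out 1 library gave 0.18 to 0.46. B-1a markers no longer passed with an estimated correlation (median 0.65, and 0.385 without control 2 and control 4) and passed in all other fits. The follicular B-2 list no longer passed with CPM above 5 (median −0.14), a sex term (−0.31), the covariate (−0.0107, by construction), an estimated correlation or fry (−0.40), and single libraries left out gave −0.52 to −0.23. Without control 2 and control 4, left out for their high scores of this list, it changed sign (0.0495). The test of the proliferation list also changed sign in that fit (−0.26). Dleu2 (2.21 to 2.79) and the seed difference (0.035 to 0.117) kept their side of the threshold throughout. Of the named genes' alternative values 994 kept their side of the threshold, 35 newly passed and 21 no longer did, and none changed sign with a call. Simulations recovered 37.5% of 2-fold changes at this depth and spread, so genes changed 2-fold or less are mostly missed.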

Other observations

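The tests in this part were chosen after the result was seen, except the splits for DESeq2 and limma voom.

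Chaperone genes lay lower in the dKO libraries. Hspa8, the constitutive HSP70 gene, was at 323.2 ± 44.3 against 637.8 ± 97.3 CPM (SD, n = 4 each, log2 fold change −0.98 ± 0.17, SE, edgeR adjusted p = 0.069), and its cochaperone Dnaja1 at 182.8 ± 36.9 against 389.5 ± 65.5 CPM (−1.09 ± 0.19, adjusted p = 0.069). A list of 31 cytosolic chaperones, drawn up after these genes had been noticed, had 28 negative members, a median of −0.35 and a camera p of 6.7e-13 (0.014 with an estimated correlation), and 13 members fell when adjusted over the list alone. Its score was 6.60 to 6.87 in the dKO libraries and 6.95 to 7.12 in the controls. The list was drawn up from genes seen to be lower in the real split, so the splits (1 of 35 gave so small a p, smallest other 3.3e-11) do not test it, and chance stays open. A list of 15 mitochondrial and ER chaperones had a median of −0.21 (p = 0.0066, and 0.30 with an estimated correlation), reached by 13 of 35 splits (smallest other 3.9e-09). Handling time at sorting, a candidate source of chaperone differences, was not tested.

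The count of 10 genes in edgeR was reached by 1 of 35 splits, the real one, and the others gave at most 0. Chance is unlikely for it but not excluded, since 35 splits allow no p below 0.029. The same held for DESeq2 (324 genes, highest other 209) and limma voom (257, highest other 102), each with 1 of 35 splits as large. The number of lists called, 3, was reached by 25 of 35 splits, and 2 splits called 10 lists each. The list p of the literature targets (3.8e-04) was reached by 4 of 35 splits, with 1.3e-05 the smallest of the others, so chance is not excluded for either. Splits with more lists than the real one point to a structure of the libraries apart from genotype, and may reflect list members that vary together between mice. Each split that set control 1 and control 3 against control 2 and control 4 called 8 to 10 lists. Those that set control 3 against all other controls called 7 to 10.

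The controls differed among themselves more than the dKO libraries did. The mean correlation with the other libraries of the group was 0.937 to 0.952 in the controls and 0.967 to 0.974 in the dKO libraries, and chi-square per degree of freedom was 107.7 to 321.3 and 31.3 to 97.3.

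Acoxl, with no count in the controls, and Mall, at 0.018 CPM in the controls and 1.36 ± 0.97 CPM (SD, n = 4) in the dKO libraries (edgeR adjusted p = 0.069), lie close together on chromosome 2, with 2 tested genes between them in the GRCm38 annotation. Of 74 placed genes with an adjusted p under 0.1, 13 are on chromosome 2, which holds 7.8% of the placed genes. Of the 50 tested genes nearest to Dleu2, 4 had an unadjusted p under 0.05, and of those nearest to Smc4, 9 did, against 10.7% of all placed genes. No such neighbour passed an adjusted p of 0.05.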
